A study of Mus musculus with 9 samples.

How the data were processed

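RNA of the caput, corpus and cauda epididymis of 9-month-old wild type C57BL/6J mice was sequenced in 3 libraries per segment. Per the labels' protocols, tissue was flash frozen, RNA was extracted with Trizol, libraries were made with a KAPA stranded mRNA kit, and single ends of 36 bases were read on an Illumina GAIIx. The submitters' processing notes name CASAVA 1.8.2, FastQC 0.11.2, Bowtie2 2.2.0 and the mm10 genome. The counting tool, the gene annotation, the strand setting and the handling of reads with several matches are not given in the sources used here.

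The authors deposited raw read counts per gene symbol for each library, per the file headers, with no normalization. The authors also deposited RPKM values (reads scaled by gene length and library size) for the same genes and libraries, per the file headers, in 2 sheets whose 216531 values were 100% identical. The counts held 24059 distinct symbols, of which 4315 had 0 counts in every library, and no column belonged to other samples. The ratio of count to RPKM was constant within a library apart from gene length. The implied library denominator, relative to caput replicate 1, was 1 to 1.194 times the total of gene counts. Segments were taken from the labels of each library. The labels name no batch or date, and give the same replicate numbers in every segment without saying what they mark.

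Before the data were examined, the tests, gene lists, alternatives and rule for named genes were fixed, under the assumption that the file would hold RPKM-like values, with a count model to be used if it held counts. The file holds counts, so the count model was used, and the alternatives written for normalized values (pseudocounts, quantile normalization, median ratio rescaling) were not applied. No symbol occurs more than once, so summing symbols changes nothing.

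Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Genes were kept by filterByExpr, which left 14168 tested and 9891 untested genes, the tested ones holding at least 99.78% of the counts of every library. Library sizes were scaled by TMM, and 1 mean per segment was fitted over all 9 libraries with the quasi-likelihood method (glmQLFit, robust = FALSE). The biological coefficient of variation was 10.1% and the prior degrees of freedom 6.75. The contrasts, all two-sided, were corpus minus caput, cauda minus corpus and cauda minus caput, with an F test over the 3 segments. An edgeR adjusted p is Benjamini-Hochberg adjusted over all tested genes, with a threshold of 0.05. A gene was called enriched in a segment when it was at least 2-fold higher than in both other segments at that threshold. Standard errors are those implied by the log2 change and its F statistic.

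Gene lists were tested with limma's camera, which compares a list's genes with all others, with a preset correlation of 0.01 and again with an estimated correlation, Benjamini-Hochberg adjusted over the lists with at least 3 tested genes. The 29 lists with members in the file were epididymal lipocalins, beta-defensins, cystatins, the secreted ribonuclease family, serine protease inhibitors, sperm-binding and maturation proteins, ROS1-ERK initial segment signalling, antioxidant enzymes, ion, water and carnitine transport, androgen and steroid handling, the secretory pathway and unfolded protein response, cholesterol synthesis, epithelial junctions, Hox genes, interferon response, immediate early and stress genes, proliferation, and markers of clear, basal, smooth muscle, fibroblast, endothelial, macrophage, lymphocyte, adipocyte, male germ, ciliated, erythrocyte and accessory gland cells. A list of mitochondrially encoded genes had no member in the file.

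Genes were named by a fixed rule. It took the 10 widest changes in each direction per contrast among genes past the threshold with a mean RPKM of at least 10 in the higher segment and no overlap between the libraries of the 2 segments. It added the 10 genes with the highest mean in each segment, up to 4 members per list and contrast, and 19 epididymal genes. Single-gene results for 3 of the genes so named are not reported here, while the fits and lists include them. Some list members named for 1 contrast are also given for another, and that use was chosen after their values were seen. Folds against a segment with 0 counts are lower bounds from 3 counts over the segment, and those against 1 to 3 counts have a 95% interval for the ratio of counts. Both cover counting error only. Means of depth-scaled counts (CPM) have the SD of 3 libraries.

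Symbols were matched to the mm10 annotation (GENCODE M21), 22908 directly and 1027 by an older name, and 23649 had a unique gene there. Coordinates are those of that annotation. Overlapping genes, and the share of a gene's 36-base windows that occur in another gene, were computed from the same annotation and genome.

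The relation of Hox paralog number to the change from caput to cauda used a two-sided test with 100000 permutations. Unchanged libraries, with the same mean per gene in every segment, were simulated 20 times and their enriched genes counted.

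The count model was tested on simulated data with 200 genes changed by known folds per contrast, drawn from the means and library sizes of the real libraries. Each gene had 1 mean over all 9 libraries, so only those 200 genes differed between the simulated segments. In the real contrasts 39.2% to 57.7% of tested genes changed, so the simulated rates may not hold there. For caput and corpus (13896 genes) it recovered 42.9%, 76%, 100% and 100% of genes changed 1.5-, 2-, 4- and 8-fold, with 5.9% false calls. For corpus and cauda (13924 genes) it recovered 56%, 77.1%, 100% and 100%, with 4.6% false calls. For caput and cauda (13927 genes) it recovered 54%, 67.3%, 96% and 100%, with 2.5% false calls.

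The alternatives were a replicate block, no filter on low counts, a stricter filter (at least 10 counts in every library of 1 segment), DESeq2 size factors, DESeq2's Wald test (version 1.42.0), only the 6 libraries compared, leaving out each library in turn, and an estimated correlation in camera. Added after the data were seen were scaling by the authors' RPKM denominators, leaving out Rn45s, leaving out replicate 3 of every segment, and Hox genes of paralog numbers 1 to 9 alone, with and without Hoxb1. Files were read and figures drawn with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.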

Results

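Messenger RNA was profiled along the epididymis, the coiled duct in which sperm released by the testis mature and are stored. The tissue came from wild type C57BL/6J mice aged 9 months and was divided into the caput, which receives sperm from the testis, the corpus in the middle, and the cauda, the distal storage segment. Each segment was represented by 3 libraries, read as single ends of 36 bases after a strand-marking mRNA library kit. Gene counts totalled 3013470, 3221708 and 3946335 in caput replicates 1 to 3, 2600061, 6076479 and 5353421 in corpus, and 5902972, 5095298 and 6072094 in cauda. In CPM, the usual depth-scaled read count, 1 count therefore stood for 0.165 to 0.385 before TMM scaling. After TMM scaling it stood for 0.1551 (corpus replicate 2) to 0.3745 (corpus replicate 1). Expression values are given as mean CPM ± SD on TMM-scaled library sizes, with n = 3 libraries per segment throughout. The labels do not state whether the libraries of a segment came from separate mice, so the p-values measure the spread between these libraries only. Across genes, log2 expression correlated at 0.978 to 0.989 between libraries of 1 segment, at 0.9 to 0.921 between corpus and cauda, at 0.731 to 0.744 between caput and corpus, and at 0.747 to 0.761 between caput and cauda.

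**Figure D1:**
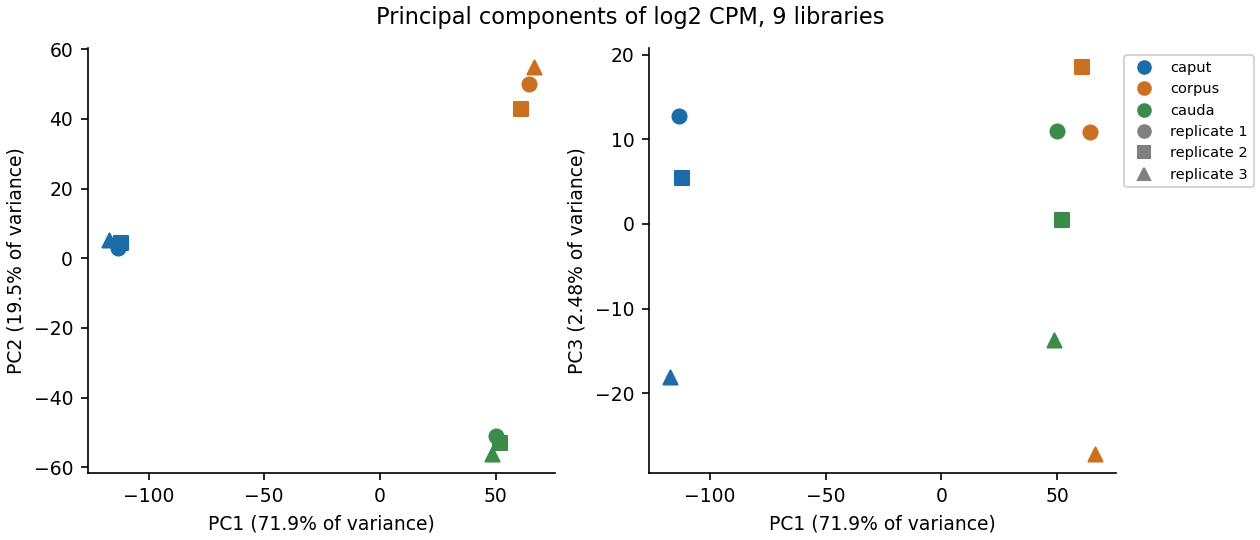
Principal components of log2 CPM for the 9 libraries, with each axis labelled by its percent of the variance, segments in colour and replicate numbers as symbols. The first component (71.9%) separates caput from both other segments, the second (19.5%) separates corpus from cauda, and on the third (2.48%) the replicate 3 libraries lie at -18.13 in caput, -27.14 in corpus and -13.77 in cauda, below the other 6.

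Caput had abundant transcripts of its own, while corpus and cauda shared most of theirs. Gpx5, the epididymal secreted glutathione peroxidase (chromosome 13, 21286429 to 21292731 on mm10), led in caput with 48960 ± 2571 CPM and took 4.63% to 4.96% of each caput library. It was followed by Adam7 at 12640 ± 899, the secreted chaperone clusterin (Clu) at 10950 ± 620.2, the defensin-like Spag11b at 9919 ± 840.4, Itm2b at 6670 ± 124, Mfge8 at 5933 ± 376, Lcn8 at 5144 ± 479.7, the clathrin adaptor subunit Ap1s2 at 4944 ± 231 and Rnase10 at 4870 ± 514 CPM. Crisp1, a cysteine-rich secretory protein that binds sperm (chromosome 17, 40293758 to 40319207), led in corpus with 26210 ± 3181 CPM and in cauda with 42300 ± 3959 CPM. Gpx3, the plasma glutathione peroxidase, came next with 14450 ± 556 CPM in corpus and 21610 ± 1128 in cauda. Corpus continued with Cuzd1 at 12090 ± 1167, Itm2b at 7226 ± 524, the sperm surface glycopeptide Cd52 at 6181 ± 637, the Kazal inhibitor Spink8 at 5865 ± 515, Adam7 at 5284 ± 757, the sterol-binding protein Npc2 at 4529 ± 647 and the carboxylesterase Ces5a at 4244 ± 771 CPM. Cauda continued with Cd52 at 17690 ± 1465, Itm2b at 10690 ± 617, Cuzd1 at 10010 ± 1006, the lipocalin-type prostaglandin D synthase Ptgds at 7819 ± 1090, Serpina1f at 7438 ± 493, Adam7 at 7151 ± 363, the class I light chain B2m at 6449 ± 511 and Ces5a at 5895 ± 267 CPM. Rn45s, the ribosomal RNA precursor, was also among the 10 highest in caput (6899 ± 1641 CPM) and corpus (7243 ± 4357) and stood at 3634 ± 1071 in cauda. The 10 highest genes together took 9.03% to 14% of a library.

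Of 14168 genes tested, 9782 (69%) differed among the segments by edgeR's quasi-likelihood F test at a Benjamini-Hochberg adjusted p threshold of 0.05. Caput-enriched genes, at least 2-fold above both other segments, numbered 1405 and held 27.1% ± 0.58 of caput counts against 2.4% in corpus and 2.63% in cauda. The 567 corpus-enriched genes held 6.58% ± 0.12 of corpus counts, 1.14% of caput counts and 1.73% of cauda counts. The 518 cauda-enriched genes held 8.84% ± 0.42 of cauda counts, 1.17% of caput counts and 2.88% of corpus counts. A segment's libraries enter both of its comparisons. Independent lists of the same sizes would share 254.8, 116.2 and 129.1 genes for caput, corpus and cauda. Simulated unchanged libraries shared 0 in 20 simulations, but with no gene changed they cannot show how far shared libraries raise the overlap. Part of the excess over independent lists may come from the shared libraries, since 3 libraries cannot be split into sets of 2 or more.

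Most of the epididymal genes fixed in advance were far higher in caput. Lcn5 stood at 3266 ± 200.2 CPM in caput, 0.986 ± 0.94 in corpus and 0.122 ± 0.107 in cauda. The matching values were 5144 ± 479.7, 0.427 ± 0.3 and 0.411 ± 0.246 for Lcn8, and 3999 ± 404, 0.176 ± 0.188 and 0 for Lcn9. In the same order of segments, the cystatin genes Cst8 and Cst11 had 1529 ± 150.3, 0.604 ± 0.255 and 1.13 ± 0.244 CPM and 2718 ± 257, 0.0628 ± 0.109 and 0 CPM, and Rnase10 had 4870 ± 514, 0.354 ± 0.0378 and 8.77 ± 0.819 CPM. The receptor tyrosine kinase Ros1 had 319.7 ± 63.2, 4.41 ± 0.723 and 3.93 ± 0.637 CPM, the protease-related Ovch2 1242 ± 134, 3.02 ± 1.03 and 2.84 ± 0.859, and the chloride channel Cftr 83.8 ± 20.7, 0.115 ± 0.101 and 0.0667 ± 0.116. Gpx5 had 23.2 ± 4.75 CPM in corpus and 306 ± 44.8 in cauda, and Clu had 179 ± 25.2 and 2270 ± 557, so that both were lower in corpus than in either neighbour. Rnase9 (1619 ± 114, 1093 ± 88.8 and 165 ± 22.9) and Crisp4 (250.5 ± 15, 185 ± 20.1 and 39.4 ± 1.74) were lowest in cauda, and Npc2 (1429 ± 57.6, 4529 ± 647 and 984 ± 147) was highest in corpus. Crisp1 and Ces5a were lowest in caput, at 924 ± 164 and 640.5 ± 19.6 CPM, and the water channel Aqp9 rose from 135 ± 25.2 to 464 ± 7.01 in corpus with 484 ± 16.4 in cauda.

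**Figure D2:**
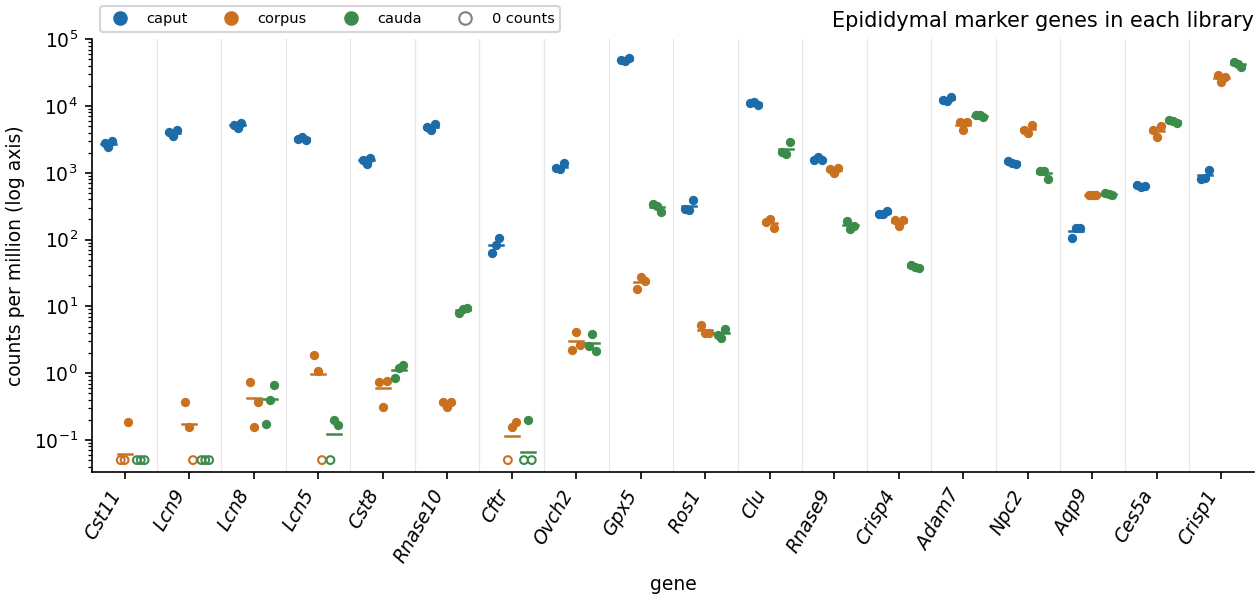
CPM of 18 epididymal genes fixed in advance, on a log axis, with a point for each library, a line at the mean of each segment (n = 3) and open circles for libraries with 0 counts, ordered by the share of the 3 segment means that lies in caput. Genes from Cst11 to Adam7 have their highest mean in caput, and Aqp9, Ces5a and Crisp1 have their lowest there.

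The comparison of caput with corpus asked how the first segment differs from the middle of the duct. Caput held Spag11b at 9919 ± 840.4 CPM against 1.02 ± 0.444 in corpus, Lcn8 at 5144 ± 479.7 against 0.427 ± 0.3, and Rnase10 at 4870 ± 514 against 0.354 ± 0.0378. Corpus held Crisp1 at 26210 ± 3181 CPM against 924 ± 164 in caput, Gpx3 at 14450 ± 556 against 269.6 ± 65.9, and Cd52 at 6181 ± 637 against 89.5 ± 17.9. Their log2 changes, corpus minus caput, were -13.38 (SE 0.17) for Spag11b, -13.74 (0.21) for Lcn8, -13.67 (0.18) for Rnase10, 4.83 (0.15) for Crisp1, 5.75 (0.16) for Gpx3 and 6.1 (0.16) for Cd52, with edgeR adjusted p between 1.48e-14 and 1.23e-11. Genes with no count in corpus included the membrane mucin Muc15, at 2277 ± 49 CPM in caput (chromosome 2, 110721340 to 110739527) and at least 10900-fold higher there, Lcn10 (987 ± 60, at least 4760-fold, chromosome 2, 25682726 to 25686081), and the colipase-like Clpsl2 (630.3 ± 63.9, at least 3060-fold). With 1 to 3 corpus counts, the caput excess was 29000-fold (95% counting interval 8020 to 239000) for Lcn9, 39400-fold (95% counting interval 7070 to 1560000) for Cst11 and 18300-fold (95% counting interval 5070 to 151000) for Lypd8. The 10 widest caput gaps held 3 further gene models without an assigned function. In the other direction Cwh43, which acts in the remodelling of glycolipid protein anchors (chromosome 5, 73406075 to 73453435), had 1069 ± 50.4 CPM in corpus and no count in caput, at least 3540-fold higher. Lactoferrin (Ltf) had 2806 ± 369.8 CPM in corpus and 2 counts in caput, a ratio of 13500-fold (95% counting interval 3740 to 112000), and the sperm-binding Bsph2 had 417 ± 22 CPM and 3 counts, a ratio of 1390-fold (95% counting interval 475 to 6740). Defb22 (2341 ± 246 CPM in corpus, 0.408 ± 0.19 in caput) and the galactosidase-like Glb1l3 (962 ± 88.1 and 0.913 ± 0.112) were also in this group of 10, with Wfdc13, Defb38, Gm10823 and the neighbouring Pate family genes Gm17252 (at least 502-fold) and Gm17365 (at least 453-fold). Fitted log2 changes that rest on few counts moved without 1 library: Cst11 from -14.78 to -16.58 and Lypd8 from -13.9 to -16.48 without corpus replicate 3, Bsph2 from 10.31 to 13.93 and Ltf from 13.59 to 12.96 without caput replicate 3, and Defb38 from 10.87 to 13.16 and Wfdc13 from 11.58 to 12.5 without caput replicate 1.

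Camera called 6 lists between caput and corpus, of which 3 held with an estimated correlation. Of 9 epididymal lipocalins, carriers of small hydrophobic molecules, 8 were lower in corpus and Ptgds was higher (612 ± 30.7 CPM in caput, 2731 ± 322 in corpus; camera adjusted p = 1.09e-32, and 0.013 with an estimated correlation). The lipocalin median was -11.89 on the log2 scale, or -10.20 with genes at 0 counts held at their bound. All 7 cystatins, inhibitors of cysteine proteases, were lower in corpus, with camera adjusted p = 3.65e-13, and 0.0255 with an estimated correlation. The smallest of these changes was that of Cst3 (382 ± 5.39 CPM in caput, 325 ± 27.7 in corpus). The 33 beta-defensins, small cationic antimicrobial peptides, were called higher in caput and split by gene, with 19 lower in corpus and 14 higher (camera adjusted p = 2.1e-06, but adjusted p = 0.359 with an estimated correlation). Examples were Spag11b and Defb25 in caput (1171 ± 108 CPM against 0.426 ± 0.609 in corpus) and Defb22 and Defb11 in corpus (242 ± 27.1 CPM against 0.961 ± 0.54 in caput). The ROS1-ERK initial segment signalling list, built around a kinase pathway of the proximal caput, had 10 of 15 genes lower in corpus, 2 higher and 3 not past the test (camera adjusted p = 8.23e-09, and 0.0305 with an estimated correlation). Ovch2 and Ros1 were among the 10, with the transcription factor Etv4 (106 ± 26.1 CPM in caput, 1.35 ± 0.475 in corpus), while the steroid reductase gene Srd5a1 (46.6 ± 4.98 and 129 ± 10.7) and the phosphatase Ptpn6 (26 ± 4.22 and 57.5 ± 6.8) were the 2 higher in corpus. Epithelial junctions split evenly, 6 higher in corpus, 6 lower and 3 not past the test, and the list was called higher in caput (camera adjusted p = 0.0343, but adjusted p = 0.557 with an estimated correlation). Cldn2, a pore-forming claudin, went from 1089 ± 61 CPM in caput to 1.18 ± 1.05 in corpus and Cldn10 from 136 ± 10.7 to 3.64 ± 1.21, whereas Ocln went from 35 ± 2.65 to 72.6 ± 9.31. The log2 change of Cldn2 was -10.18, -10.77 without corpus replicate 1 and -9.46 without corpus replicate 2. The epithelial junctions call ended with no low-count filter (camera adjusted p = 0.195) and without corpus replicate 2 (camera adjusted p = 0.0747), and its camera adjusted p ranged from 0.0165 to 0.195 over the alternatives. Adjusted over the list alone, the counts of these 5 lists were the same.

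The remaining lists of secreted and epithelial functions were not called by camera between caput and corpus. Serine protease inhibitors had 17 of 28 genes higher in corpus and 8 lower (camera adjusted p = 0.075). Wfdc16 rose from 14.5 ± 2.46 to 2492 ± 163 CPM and Spink11 and Spink12 fell from 1121 ± 52.6 and 276 ± 14 to 18.8 ± 0.782 and 3.18 ± 1.29. Sperm-binding and maturation proteins had 10 of 20 higher, 9 lower and 1 not past the test, or 11 and 9 adjusted over the list alone (camera adjusted p = 0.545). Pate2 rose from 2.25 ± 0.68 to 1369 ± 99.8 CPM, and Adam28 was at 2391 ± 286 in caput and 0.908 ± 0.846 in corpus, a log2 change of -11.23 that was -12.32 without corpus replicate 3. The secreted ribonuclease family had 3 of 9 higher, 4 lower and 2 not past the test, or 4 and 4 adjusted over the list alone (camera adjusted p = 0.0558), and its median (0.19) and mean (-2.24) differed in sign. Rnase13 had 314 ± 16.3 CPM in caput and no count in corpus, at least 1510-fold lower, and Rnase11 rose from 8.1 ± 0.856 to 59.7 ± 5.01. Antioxidant enzymes (13 of 30 higher, 10 lower) held Gpx5 and Gpx3 at opposite ends, and the quinone reductase Nqo1 rose from 16.6 ± 1.83 to 236 ± 16.2 CPM. Ion, water and carnitine transport (9 of 21 higher, 8 lower) included Slc38a5, at 3056 ± 152 CPM in caput and 5.13 ± 3.14 in corpus, and the carnitine transporter Slc22a5, at 27.5 ± 3.49 and 377 ± 12.1. Androgen and steroid handling (7 of 18 higher and 9 lower, or 8 and 9 adjusted over the list alone) ranged from the oestrogen receptor Esr2 (9.86 ± 1.46 and 1.13 ± 0.64 CPM) to the oestrogen sulfotransferase Sult1e1 (1.03 ± 0.572 and 118 ± 4.67). The secretory pathway and unfolded protein response had 12 of 21 lower in corpus and 3 higher, with Dnajc3 at 498 ± 38.3 and 215 ± 34 CPM and Canx at 807 ± 51.8 and 1786 ± 178. Cholesterol synthesis had 6 of 18 higher and 8 lower, and Hox genes had 14 of 29 lower and 5 higher. In order from antioxidant enzymes to Hox genes the camera adjusted p were 0.272, 0.92, 0.545, 0.245, 0.92 and 0.167. The median log2 change differed in sign from the mean or from the camera direction for sperm-binding proteins, antioxidant enzymes, ion transport and steroid handling.

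Markers of other cells also differed between the caput and corpus libraries. Of 14 male germ cell and sperm markers, 13 were higher in corpus, such as Odf1 (18.1 ± 1.85 CPM in caput, 93.2 ± 12 in corpus) and Smcp (38.7 ± 4.68 and 171 ± 19), with camera adjusted p = 0.0427, but adjusted p = 0.831 with an estimated correlation. The male germ cell and sperm markers call ended without caput replicate 1 (camera adjusted p = 0.0535, range 0.00281 to 0.0535 over the alternatives). Immediate early and stress genes had 12 of 15 higher in corpus and 2 lower, with Fos at 34.6 ± 8.29 and 379.9 ± 76.1 CPM and Fosb at 12.9 ± 2.15 and 154 ± 29.2, whereas Egr2 was at 573 ± 21.7 in caput and 41.5 ± 9.78 in corpus (camera adjusted p = 0.0751). Ciliated cell markers had 7 of 9 lower in corpus (camera adjusted p = 0.0558), the regulator Foxj1 standing at 28.2 ± 9.42 CPM in caput and 0.291 ± 0.0945 in corpus. Clear cell markers had 6 of 9 higher and 2 lower (camera adjusted p = 0.0751), the carbonic anhydrase Car2 rising from 43 ± 5.08 to 343 ± 20.2 CPM and Atp6v0d2 falling from 168 ± 2.87 to 50.5 ± 2.43, and basal cell markers had 6 of 9 higher and 1 lower, Krt15 rising from 13.9 ± 1.02 to 44 ± 2.42 (camera adjusted p = 0.443). Smooth muscle markers had 3 of 12 lower and 1 higher, or 2 and 1 adjusted over the list alone, with Actg2 at 1243 ± 108 CPM in caput and 17.2 ± 9.82 in corpus. Macrophage and dendritic markers had 6 of 15 lower and 2 higher, or 5 and 2 adjusted over the list alone, with Cd68 at 37.6 ± 7.71 and 10.7 ± 0.512 CPM. Fibroblast and matrix markers had 4 of 11 higher and 1 lower, or 3 and 1 adjusted over the list alone, with Pdgfra at 349 ± 25.2 and 40.3 ± 20.6 CPM. Endothelial markers had 1 of 9 higher, Esam, and 1 lower, interferon response genes had 1 of 16 higher and 1 lower, and proliferation had 3 of 5 lower, with Mki67 at 9.1 ± 2.88 and 3.57 ± 0.574 CPM. Adipocyte markers had 2 of 4 higher and 1 lower, or 2 and 2 adjusted over the list alone, and accessory gland secretory markers had 1 of 3 higher, or 0 adjusted over the list alone. That gene was Svs1, with a log2 change of 5.09 (edgeR adjusted p = 0.0333), or 3.68 (edgeR adjusted p = 0.112) without corpus replicate 3. The Svs1 call also ended without caput replicate 1 (edgeR adjusted p = 0.0669), caput replicate 2 (0.0685) or caput replicate 3 (0.0771) and without replicate 3 of every segment (3.64, edgeR adjusted p = 0.221). The 8 lists from smooth muscle to accessory gland were not called, with camera adjusted p, in the order named, of 0.446, 0.609, 0.811, 0.92, 0.92, 0.707, 0.92 and 0.92. The lymphocyte and erythrocyte lists each kept 1 tested gene, Cd3e (3.9 ± 1.91 and 1.05 ± 0.859 CPM) and Alas2 (1.86 ± 0.734 and 23 ± 0.728), which is too few for a list test. The fall of Cd3e (-1.76, edgeR adjusted p = 0.0181) was lost without caput replicate 2 (edgeR adjusted p = 0.0693), caput replicate 3 (0.0784), corpus replicate 3 (0.0611) or replicate 3 of every segment (-1.05, edgeR adjusted p = 0.136). Median and mean differed in sign, or the median was 0, for the adipocyte and accessory gland lists.

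Between caput and corpus, 8173 genes changed (57.7% of those tested) by edgeR's quasi-likelihood test at an adjusted p threshold of 0.05, 4180 of them higher in corpus and 3993 higher in caput. At least 2-fold changes numbered 3825, with 1805 higher in corpus and 2020 in caput, and 93 and 135 genes differed by over 100-fold in the 2 directions. Scaling by the library denominators behind the authors' RPKM values shifted the median of all tested genes from 0.005 to -0.134 on the log2 scale and the share of changed genes higher in corpus from 51.1% to 40.5%. Muc15, Cd52, Pate2, Gm17252, Gm17365, Srd5a1 and Pdgfra overlap other annotated genes and Defb11 (27.3%) and Slc22a5 (33.9%) share read-length sequence with relatives, so their counts are uncertain.

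The comparison of corpus with cauda asked what changes between the middle of the duct and the site of sperm storage. Cauda held Serpine2, an inhibitor of serine proteases, at 971 ± 120.3 CPM against 21.2 ± 4.86 in corpus, D730048I06Rik at 1996 ± 132 against 5.05 ± 1.5, and Azgp1, a secreted zinc-binding glycoprotein, at 157 ± 13.2 against 0.281 ± 0.247. Corpus held Defb22 at 2341 ± 246 CPM against 31.2 ± 13.8 in cauda, the carbonic anhydrase Car4 at 934 ± 53.8 against 28.7 ± 3.19, and the sarcomere protein gene Myom2 at 269 ± 11.4 against 5.39 ± 1.23. Their log2 changes, cauda minus corpus, were 5.48 (SE 0.15) for Serpine2, 8.72 (0.14) for D730048I06Rik, 8.71 (0.22) for Azgp1, -6.21 (0.23) for Defb22, -5.02 (0.10) for Car4 and -5.62 (0.17) for Myom2, with edgeR adjusted p between 5.2e-13 and 3.63e-10. The Kazal inhibitor gene Spink14 (chromosome 18, 44027869 to 44032417) had 326 ± 92.6 CPM in cauda and no count in corpus, at least 1550-fold higher, and Lce6a had 15.6 ± 6.34, at least 75.8-fold higher. With 1 or 2 corpus counts, the cauda excess was 993-fold (95% counting interval 275 to 8200) for the crystallin gene Cryba4, 697-fold (95% counting interval 125 to 27600) for S100a8, which neutrophils express strongly, and 314-fold (95% counting interval 55.9 to 12400) for Defb18. Smpx, a small protein of striated muscle, completed the named genes with 175 ± 13.7 CPM in cauda and 0.405 ± 0.0517 in corpus, beside 2 gene models. The 10 widest corpus gaps also held Defb23 (208 ± 52.8 CPM in corpus, 1.85 ± 1.61 in cauda), the Piwi protein gene Piwil2 (111 ± 11.2 and 4.85 ± 0.928), the adenylate kinase Ak8 (65.8 ± 4.7 and 2.69 ± 0.604), the protocadherin Cdhr2 (91.9 ± 9.53 and 2.21 ± 1.22), BC048679 (920.1 ± 101 and 16.1 ± 4.8), Gm17365 (139 ± 15.8 and 1.68 ± 0.699) and Gm10823. Without 1 library the log2 change of Defb23 moved from -6.78 to -7.79 (cauda replicate 3), that of Cryba4 from 9.69 to 12.37 (corpus replicate 1), that of S100a8 from 8.98 to 10.73 (corpus replicate 2) and that of Defb18 from 7.81 to 9.61 (corpus replicate 3).

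Camera called 9 lists between corpus and cauda, and with an estimated correlation it called 0 of 27, with 2 at an unadjusted p under 0.05. Smooth muscle markers were 11 of 12 higher in cauda, or 12 adjusted over the list alone (camera adjusted p = 1.1e-05, but adjusted p = 0.604 with an estimated correlation), with a median change of 2.73 that was 1.84 without replicate 3 of every segment. Tagln went from 79.2 ± 35.2 to 644 ± 168 CPM, Actg2 from 17.2 ± 9.82 to 205 ± 67.6 and Cnn1 from 26.9 ± 14.8 to 253 ± 83.8, and corpus replicate 3 held the lowest value of all 9 libraries for Tagln, Actg2 and Cnn1. Without replicate 3 of every segment the log2 changes of Actg2 and Cnn1 were 2.86 and 2.51, against 3.59 and 3.23 with all libraries. Serine protease inhibitors were 14 of 28 higher in cauda, 10 lower and 4 not past the test (camera adjusted p = 1.48e-06, but adjusted p = 0.151 with an estimated correlation), Serpine2 rising and Spint4 falling from 11.6 ± 2.25 to 0.794 ± 0.365 CPM. Of 10 accessory gland secretory markers in the file only 3 had enough counts to be tested. All 3 were higher in cauda (camera adjusted p = 3.24e-07, but adjusted p = 0.151 with an estimated correlation). Svs1 and Svs4 passed the low-count filter only through their cauda counts, so their direction was largely set by the filter. Svs1 stood at 202 ± 33.2 CPM against 0.856 ± 0.89 in corpus and Svs4 at 6.33 ± 0.448 against 0. The log2 change of Svs1 was 7.76, and 9.14 without corpus replicate 3. Cholesterol synthesis had 11 of 18 higher and 2 lower (camera adjusted p = 0.00919, but adjusted p = 0.604 with an estimated correlation). Nsdhl stood at 151 ± 0.66 CPM in corpus and 343 ± 30.4 in cauda. Interferon response genes had 10 of 16 higher and 0 lower, or 12 and 0 adjusted over the list alone (camera adjusted p = 0.0134, but adjusted p = 0.622 with an estimated correlation). Ifit1 stood at 6.91 ± 0.548 and 20.2 ± 3.01 CPM. Male germ cell and sperm markers had 10 of 14 higher and 0 lower (camera adjusted p = 0.0235, but adjusted p = 0.604 with an estimated correlation). The sperm chromatin genes Prm1 stood at 10.4 ± 1.36 and 25.4 ± 3.76 CPM and Prm2 at 78.4 ± 7.66 and 182 ± 61.4.

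Lipocalins, Hox genes and sperm-binding proteins made up the other 3 calls. All 3 ended with the replicate block, lipocalins at a camera adjusted p of 0.0714 and sperm-binding proteins at 0.332. Of 9 epididymal lipocalins, 4 were higher in cauda and 0 lower, or 4 and 1 adjusted over the list alone (camera adjusted p = 0.0134, but adjusted p = 0.57 with an estimated correlation). Apod stood at 67.3 ± 15.7 CPM in corpus and 357 ± 153 in cauda and Lcn12 at 82.5 ± 3.42 and 244 ± 9.4. Hox genes had 8 of 29 higher in cauda and 2 lower (camera adjusted p = 0.0249, but adjusted p = 0.609 with an estimated correlation). Hoxb9 rose from 24.9 ± 4.32 to 159.8 ± 22.2 CPM and Hoxd10 from 1.95 ± 1.43 to 21.8 ± 4.3, the log2 change of Hoxd10 being 3.4, 4.39 without corpus replicate 2 and 2.79 without replicate 3 of every segment. The Hox genes call also ended without corpus replicate 3 (camera adjusted p = 0.0613) and without cauda replicate 1 (camera adjusted p = 0.0714). Sperm-binding and maturation proteins were called higher in corpus with 8 of 20 lower in cauda and 7 higher, or 9 and 7 adjusted over the list alone (camera adjusted p = 0.0249, but adjusted p = 0.604 with an estimated correlation). Pate2 fell from 1369 ± 99.8 to 269 ± 63.3 CPM and Clu rose from 179 ± 25.2 to 2270 ± 557. That call on sperm-binding and maturation proteins also ended without cauda replicate 2 (camera adjusted p = 0.0524) and without replicate 3 of every segment (camera adjusted p = 0.0805).

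Lists not called between corpus and cauda still held large single changes. Beta-defensins had 8 of 33 higher in cauda, 10 lower and 15 not past the test (camera adjusted p = 0.0988). Defb2 rose from 185 ± 22.8 to 919 ± 63.4 CPM while Defb22 fell. The secreted ribonuclease family had 3 of 9 higher and 3 lower (camera adjusted p = 0.23). Rnase9 fell from 1093 ± 88.8 to 165 ± 22.9 CPM and Rnase10 rose from 0.354 ± 0.0378 to 8.77 ± 0.819. In other abundant caput-enriched genes, cauda stood at a median of 0.16% of caput. That share of the 4870 CPM of Rnase10 in caput covers its rise, so caput tissue carried into the cauda libraries stays open for Rnase10. Antioxidant enzymes had 12 of 30 higher and 7 lower (camera adjusted p = 0.105), with Gpx5 rising and Nqo1 falling from 236 ± 16.2 to 62 ± 13.7 CPM. Epithelial junctions had 6 of 15 higher and 5 lower (camera adjusted p = 0.105). Cldn4 rose from 42.1 ± 3.75 to 147 ± 9.53 CPM and Cdh1 fell from 528 ± 41 to 339.9 ± 16.5. Androgen and steroid handling had 5 of 18 higher and 7 lower, or 8 and 7 adjusted over the list alone (camera adjusted p = 0.109). Srd5a1 fell from 129 ± 10.7 to 14.5 ± 2.73 CPM and the retinoid receptor Rarg rose from 21.5 ± 6.42 to 72.2 ± 7.58. Ion, water and carnitine transport had 9 of 21 higher and 6 lower (camera adjusted p = 0.862). The anion exchanger Slc26a3 stood at 29.6 ± 1.74 and 120 ± 8.47 CPM and the potassium channel Kcnj16 at 20.7 ± 3.62 and 0.737 ± 0.402. ROS1-ERK initial segment signalling had 5 of 15 higher and 2 lower (camera adjusted p = 0.816). Ggt1 stood at 4.13 ± 0.668 and 32.5 ± 7.87 CPM, and cystatins had 1 of 7 higher, Cst3, and 0 lower (camera adjusted p = 0.745). The secretory pathway and unfolded protein response had 6 of 21 higher and 3 lower (camera adjusted p = 0.681), and immediate early and stress genes had 2 of 15 higher and 3 lower (camera adjusted p = 0.839). Basal cell markers had 6 of 9 lower and 1 higher (camera adjusted p = 0.202). Itga6 fell from 124 ± 4.21 to 34.2 ± 0.963 CPM. Clear cell markers had 5 of 9 higher and 2 lower (camera adjusted p = 0.862). Car2 fell from 343 ± 20.2 to 76.5 ± 11.9. Fibroblast and matrix markers had 3 of 11 higher and 0 lower, or 2 and 0 adjusted over the list alone (camera adjusted p = 0.141). Dcn stood at 284 ± 121 and 604 ± 89.1 CPM. Macrophage and dendritic markers had 4 of 15 higher and 0 lower (camera adjusted p = 0.105). Cd74 stood at 132 ± 30.4 and 193 ± 24.4. Endothelial markers had 2 of 9 lower, Egfl7 and Esam, ciliated cell markers had 1 of 9 higher and 1 lower, proliferation had 1 of 5 higher, Mki67, and adipocyte markers had 1 of 4 lower, with camera adjusted p of 0.681, 0.451, 0.504 and 0.862. Cd3e had 1.05 ± 0.859 CPM in corpus and 2.59 ± 0.953 in cauda, and Alas2 had 23 ± 0.728 and 3.75 ± 0.733. Median and mean, or the camera direction, differed in sign for cystatins, ribonucleases, ion transport, steroid handling and clear cell markers.

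Between corpus and cauda, 5552 genes changed (39.2% of those tested) by edgeR's quasi-likelihood test at an adjusted p threshold of 0.05, 2661 of them higher in cauda and 2891 in corpus. At least 2-fold changes numbered 1944, with 1032 higher in cauda and 912 in corpus, and 25 and 4 genes differed by over 100-fold. Scaling by the denominators of the authors' RPKM values moved the share of changed genes higher in cauda from 47.9% to 57.8%, below a shift of 10 points, with a median log2 change of 0.065. Ak8, Tagln, Cd52, Cd74, Gm17365, Pate2, Srd5a1 and Egfl7 overlap other annotated genes and Defb2 shares 25.2% of its read-length sequence with relatives, so their counts are uncertain.

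The comparison of caput with cauda set the ends of the duct against each other. Caput held Gpx5, Spag11b, Lcn8 and the amino acid transporter Slc38a5 at 48960 ± 2571, 9919 ± 840.4, 5144 ± 479.7 and 3056 ± 152 CPM, against 306 ± 44.8, 1.05 ± 0.263, 0.411 ± 0.246 and 2.63 ± 1.42 in cauda. Cauda held Crisp1, Gpx3, Cd52 and Serpina1f at 42300 ± 3959, 21610 ± 1128, 17690 ± 1465 and 7438 ± 493 CPM, against 924 ± 164, 269.6 ± 65.9, 89.5 ± 17.9 and 694 ± 59.5 in caput. The log2 changes, cauda minus caput, were -7.32 (SE 0.16) for Gpx5, -10.15 (0.30) for Slc38a5, 5.52 (0.16) for Crisp1, 7.62 (0.17) for Cd52 and 3.42 (0.10) for Serpina1f, with edgeR adjusted p between 3.94e-13 and 1.07e-11. Among the widest gaps, Lcn9 (chromosome 2, 25823153 to 25825537), Cst11, Muc15, Lcn10, Cst12 and Clpsl2 had no count in cauda and were at least 22600-, 15400-, 12800-, 5570-, 4200- and 3580-fold higher in caput. Lcn5 had 2 cauda counts and a caput excess of 27500-fold (95% counting interval 7620 to 227000), and 3 gene models were also among the 10. In cauda, Cwh43 (885 ± 23.1 CPM), the seminal vesicle protein gene Svs1 (202 ± 33.2), Smpx (175 ± 13.7), Khdc1a (101 ± 7.89), the fatty acid hydroxylase gene Cyp4a12b (115 ± 16.4) and Gm17252 (79.6 ± 21.3) had no count in caput and were at least 2940-, 664-, 579-, 338-, 381- and 264-fold higher in cauda. Ltf, Spink14 and Cyp4a12a had 1 or 2 caput counts and cauda excesses of 15500-fold (95% counting interval 4290 to 128000), 3210-fold (95% counting interval 576 to 127000) and 2880-fold (95% counting interval 517 to 114000), and Gm5615 completed the 10. Without 1 library the log2 change of Spink14 moved from 11.32 to 13.57 (caput replicate 3), that of Cyp4a12a from 11.15 to 13.44 (caput replicate 1) and that of Ltf from 13.73 to 13.11 (caput replicate 3).

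Camera called 11 lists between caput and cauda, of which 5 held with an estimated correlation. Epididymal lipocalins had 6 of 9 lower in cauda and 1 higher, Ptgds, with camera adjusted p = 1.17e-27, and 0.00452 with an estimated correlation. Beta-defensins had 21 of 33 lower and 12 higher (camera adjusted p = 2.68e-11, and 0.0281 with an estimated correlation), Defb25 having 3 cauda counts and a caput excess of 6640-fold (95% counting interval 2270 to 32200) and Defb2 rising from 24.6 ± 0.702 to 919 ± 63.4 CPM. Cystatins had 6 of 7 lower and 0 higher (camera adjusted p = 6.06e-14, and 0.0142 with an estimated correlation). ROS1-ERK initial segment signalling had 10 of 15 lower and 1 higher, or 11 and 1 adjusted over the list alone (camera adjusted p = 3.27e-10, and 0.0142 with an estimated correlation). Ros1 stood at 319.7 ± 63.2 CPM in caput and 3.93 ± 0.637 in cauda and the growth factor receptor Fgfr2, the 1 gene higher in cauda, at 70.7 ± 5.67 and 199 ± 28.9. The secreted ribonuclease family was called higher in caput (camera adjusted p = 5.84e-04, and 0.0412 with an estimated correlation) with 3 of 9 lower in cauda and 4 higher, so that its median (0.43) and its mean (-1.83) differed in sign. Rnase10 and Rnase13 fell to 8.77 ± 0.819 and 0.112 ± 0.0972 CPM, and Rnase1 rose from 0.713 ± 0.207 to 12.7 ± 1.1. That secreted ribonuclease family call ended with no low-count filter (camera adjusted p = 0.205, range 6.46e-05 to 0.205 over the alternatives).

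Serine protease inhibitors had 17 of 28 higher in cauda and 6 lower, or 17 and 7 adjusted over the list alone (camera adjusted p = 3.28e-07, but adjusted p = 0.062 with an estimated correlation). Wfdc16 stood at 14.5 ± 2.46 CPM in caput and 2078 ± 131 in cauda and Spink2 at 415 ± 72.9 and 10.9 ± 1.28. All 14 male germ cell and sperm markers were higher in cauda (camera adjusted p = 9.36e-05, but adjusted p = 0.442 with an estimated correlation), such as Odf1 at 18.1 ± 1.85 and 150.4 ± 33.3 CPM and Prm2 at 27.1 ± 4.45 and 182 ± 61.4. The 3 tested of 10 accessory gland secretory markers were all higher in cauda (camera adjusted p = 0.00204, but adjusted p = 0.0603 with an estimated correlation). Svs1 and Svs4 passed the low-count filter only through their cauda counts, so here too their direction was largely set by the filter. Svs4 had 6.33 ± 0.448 CPM in cauda and no count in caput, at least 21-fold higher. Sperm-binding and maturation proteins were called higher in caput with 10 of 20 lower in cauda and 9 higher, or 11 and 9 adjusted over the list alone (camera adjusted p = 0.0342, but adjusted p = 0.481 with an estimated correlation). Adam28 went from 2391 ± 286 CPM in caput to 0.291 ± 0.0789 in cauda, while Cd52 rose. This call on sperm-binding and maturation proteins ended with no low-count filter and without corpus replicate 2 or any cauda replicate (camera adjusted p of 0.585, 0.0602, 0.148, 0.0759 and 0.112, range 0.00181 to 0.585 over the alternatives). Antioxidant enzymes had 17 of 30 higher in cauda and 9 lower, or 19 and 9 adjusted over the list alone (camera adjusted p = 0.0425, but adjusted p = 0.503 with an estimated correlation). Gsta3 stood at 32.4 ± 1.53 CPM in caput and 194 ± 10.8 in cauda. The antioxidant enzymes call ended without caput replicate 2 (camera adjusted p = 0.0633), corpus replicate 1 (0.0548) or corpus replicate 2 (0.0559). It also ended with a stricter low-count filter (camera adjusted p = 0.0511), with only the 6 libraries compared (0.0718) and with RPKM denominators as library sizes (0.0635), antioxidant enzymes ranging from 0.0065 to 0.0718 over the alternatives. Immediate early and stress genes had 13 of 15 higher in cauda and 1 lower, or 13 and 2 adjusted over the list alone (camera adjusted p = 0.0425, but adjusted p = 0.746 with an estimated correlation). Fos stood at 34.6 ± 8.29 and 448 ± 204 CPM, Atf3 at 7.41 ± 0.29 and 143 ± 77 and Egr2 at 573 ± 21.7 and 54.7 ± 11.9. The immediate early and stress genes call ended with a stricter low-count filter (camera adjusted p = 0.0511) and without caput replicate 2 (0.0574), caput replicate 3 (0.0524) or corpus replicate 2 (0.0559), range 0.00103 to 0.0574.

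Lists not called between caput and cauda included several cell type markers. Smooth muscle markers had 10 of 12 higher in cauda and 1 lower (camera adjusted p = 0.0913). Tagln stood at 117 ± 18.8 CPM in caput and 644 ± 168 in cauda and Actg2 at 1243 ± 108 and 205 ± 67.6. Fibroblast and matrix markers had 8 of 11 higher and 1 lower, or 9 and 1 adjusted over the list alone (camera adjusted p = 0.177). Pi16 stood at 8.84 ± 1.84 and 45 ± 9.41 CPM and Pdgfra at 349 ± 25.2 and 55.1 ± 13.1. Clear cell markers had 6 of 9 higher and 1 lower (camera adjusted p = 0.0535). The proton pump subunit Atp6v1c2 stood at 8.12 ± 1.2 and 73.4 ± 1.7 CPM. Ciliated cell markers had 7 of 9 lower and 0 higher, or 7 and 1 adjusted over the list alone (camera adjusted p = 0.0834). Foxj1 stood at 28.2 ± 9.42 and 0.716 ± 0.0743 CPM. Basal cell markers had 3 of 9 higher and 3 lower (camera adjusted p = 0.901). Krt15 stood at 13.9 ± 1.02 and 96.1 ± 13.9 CPM and Trp63 at 123 ± 13.7 and 53.5 ± 2.16. Macrophage and dendritic markers had 5 of 15 higher and 4 lower (camera adjusted p = 0.887), endothelial markers 1 of 9 higher and 2 lower (0.901), interferon response genes 8 of 16 higher and 0 lower, or 7 and 0 adjusted over the list alone (0.137), adipocyte markers 0 of 4 higher and 2 lower (0.887) and proliferation 0 of 5 higher and 1 lower (0.942). Cholesterol synthesis had 10 of 18 higher and 2 lower (camera adjusted p = 0.0913). Dhcr7 stood at 18.1 ± 2.5 and 48.6 ± 7.14 CPM. Ion, water and carnitine transport had 8 of 21 higher and 10 lower (camera adjusted p = 0.901). Slc22a5 stood at 27.5 ± 3.49 and 306 ± 38.7 CPM. Androgen and steroid handling had 6 of 18 higher and 7 lower, or 7 and 8 adjusted over the list alone (camera adjusted p = 0.964). The steroid reductase gene Srd5a2 stood at 77 ± 3 and 16.4 ± 2.21 CPM. Epithelial junctions had 5 of 15 higher and 5 lower, or 6 and 7 adjusted over the list alone (camera adjusted p = 0.0794). Cldn8 stood at 91 ± 4.8 and 430.3 ± 19.9 CPM and Cdh16 at 308 ± 28.7 and 26.3 ± 4.24. The secretory pathway and unfolded protein response had 1 of 21 higher and 10 lower (camera adjusted p = 0.301). Hsp90b1 stood at 2076 ± 126 and 950.2 ± 45.2 CPM. Cd3e had 3.9 ± 1.91 CPM in caput and 2.59 ± 0.953 in cauda, and Alas2 had 1.86 ± 0.734 and 3.75 ± 0.733. The rise of Alas2 (1.03, edgeR adjusted p = 0.0167) was lost without caput replicate 3 (0.71, edgeR adjusted p = 0.132) and without replicate 3 of every segment (0.62, edgeR adjusted p = 0.224). Median and mean, or the camera direction, differed in sign for steroid handling and epithelial junctions.

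**Figure D3:**
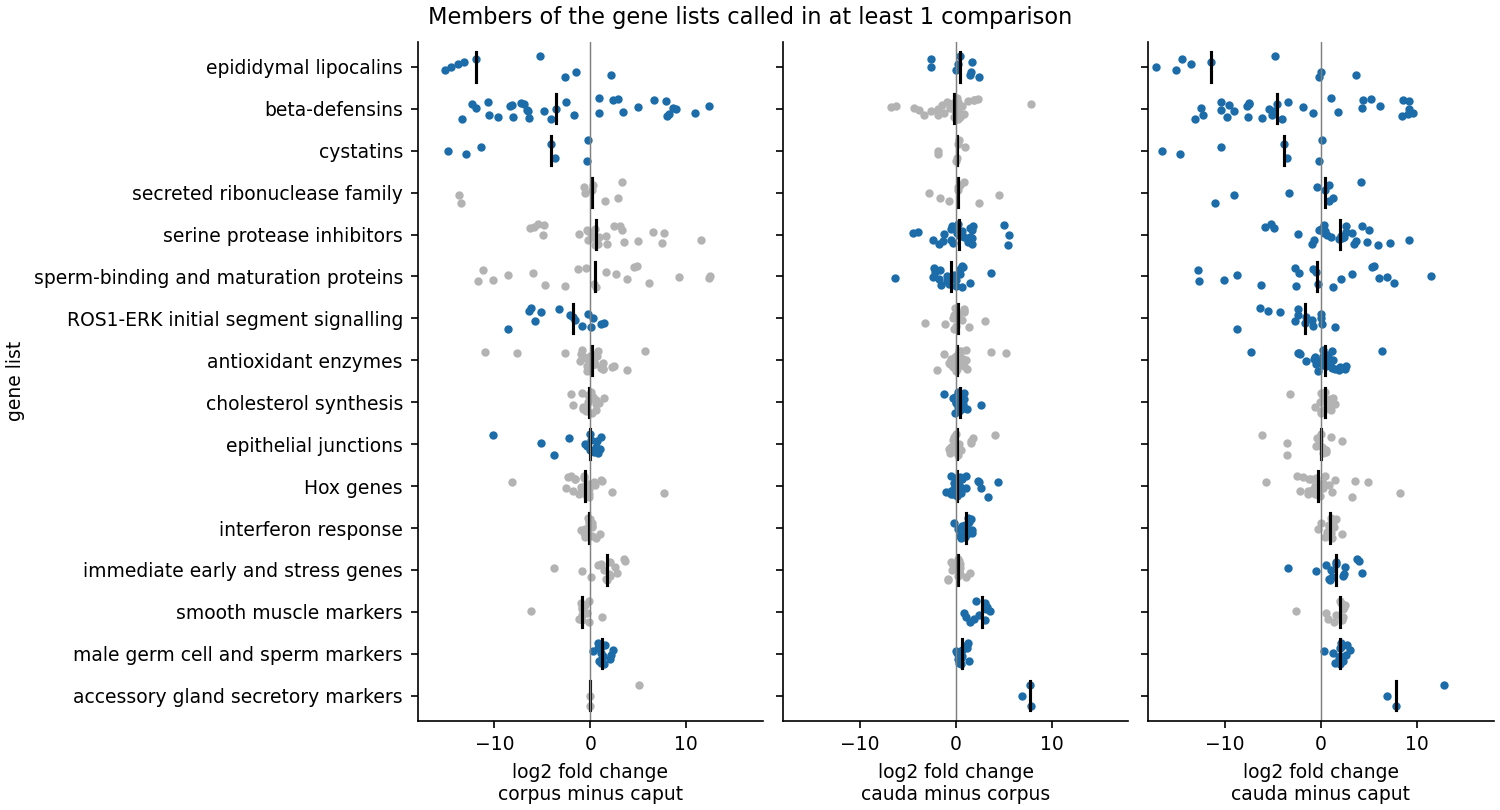
Log2 fold changes of the tested members of the 16 gene lists that camera called in at least 1 comparison, with a point per gene, a black bar at the list median and blue where that list was called in that comparison. Lipocalins, cystatins and ROS1-ERK genes lie mostly to the left of 0 in both comparisons with caput, and smooth muscle markers to the right of 0 from corpus to cauda (median 2.73).

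Hox genes, which set position along the body axis, differed between the ends of the duct in both directions, with the largest rises toward cauda at paralog numbers 10 and 11. Of 29 tested Hox genes, 8 were higher in cauda and 13 lower, or 9 and 13 adjusted over the list alone, and camera did not call the list (camera adjusted p = 0.901), whose median (-0.33) and mean (0.11) differed in sign. Hoxc10 had 8.45 ± 1.67 CPM in cauda and no count in caput, at least 27.9-fold higher, and Hoxd10 had 21.8 ± 4.3 and 2.27 ± 0.676. Hoxb1 had 7.66 ± 1.11 CPM in caput and 2 counts in cauda, a ratio of 64.4-fold (95% counting interval 17.2 to 542), and Hoxa2 had 6.19 ± 3.35 and 1.05 ± 0.288. Across the 29 genes, which are not independent replicates, paralog number correlated with the log2 change from caput to cauda at Pearson's r = 0.642 (permutation p = 4e-05, adjusted 8e-05 over the 2 coefficients) and Spearman's rho = 0.555 (permutation p = 0.00233, adjusted 0.00233). Leaving out the 2 genes with paralog numbers farthest from the median gave r = 0.643, but without the 4 genes of numbers 10 and 11 the other 25 gave r = 0.42 (permutation p = 0.0318, unadjusted) and rho = 0.306 (permutation p = 0.139, unadjusted). Without Hoxb1 as well, the remaining 24 gave r = 0.267 (permutation p = 0.207, unadjusted). Hoxa11, Hoxc9, Hoxc10 and Hoxd3 overlap other annotated genes and Hoxd3 shares 60.9% of its read-length sequence with other genes, so their counts are uncertain.

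**Figure D4:**
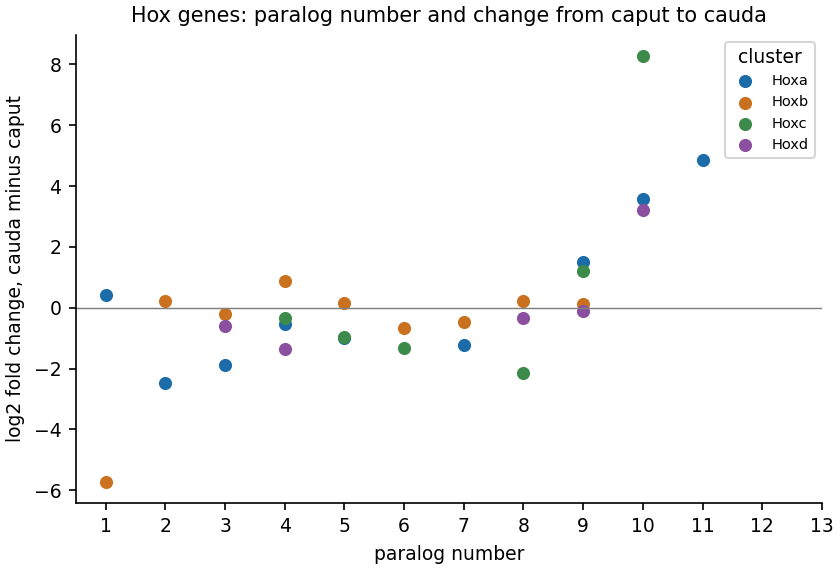
Log2 fold change from caput to cauda of the 29 tested Hox genes against their paralog number, with a point per gene and colours for the 4 clusters. Genes of paralog number 9 and below lie between -5.72 and 1.49, and the 4 genes of numbers 10 and 11 lie between 3.23 and 8.28.

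Between caput and cauda, 7745 genes changed (54.7% of those tested) by edgeR's quasi-likelihood test at an adjusted p threshold of 0.05, 3898 of them higher in cauda and 3847 in caput. At least 2-fold changes numbered 3560, with 1773 higher in cauda and 1787 in caput, and 85 and 120 genes differed by over 100-fold. Scaling by the denominators of the authors' RPKM values moved the share of changed genes higher in cauda from 50.3% to 44.3%, with a median log2 change of -0.061. Muc15, Cd52, Gm17252, Tagln, Pdgfra, Atp6v1c2, Fgfr2 and Hsp90b1 overlap other annotated genes and Cyp4a12a (58.4%), Cyp4a12b (59.1%), Khdc1a (53.2%) and Slc22a5 (33.9%) share read-length sequence with relatives, so their counts are uncertain.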

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

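The alternatives without Rn45s, without replicate 3 of every segment, with Hox genes of numbers 1 to 9 alone and with the authors' RPKM denominators as library sizes were chosen after the data were seen, and the others before. No gene called in both the reported fit and an alternative changed direction, under any alternative. Genes changed between caput and corpus numbered 7282 (DESeq2's Wald test) to 8576 (no low-count filter) over all alternatives, against 8173 reported. Between corpus and cauda the range was 4574 to 5946 against 5552, and between caput and cauda 6830 to 8178 against 7745. Genes that differ among the segments ranged from 8783 to 10466 against 9782, caput-enriched genes from 1322 to 1582 against 1405, corpus-enriched genes from 499 to 649 against 567, and cauda-enriched genes from 457 to 638 against 518. With all paralog numbers, the correlation of Hox paralog number with change ranged from 0.586 to 0.653 against 0.642. With numbers 1 to 9 alone it was 0.42, and 0.267 without Hoxb1 as well.

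Leaving out 1 library gave 7475 to 8324, 4773 to 5568 and 6991 to 7999 changed genes for caput and corpus, corpus and cauda, and caput and cauda. Gene lists called then numbered 5 to 9, 8 to 12 and 8 to 12, against 6, 9 and 11 reported.

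Camera with an estimated correlation called 3, 0 and 5 lists, with 4, 2 and 7 at an unadjusted p under 0.05. Its larger variance inflation for lists whose members vary together follows from its construction. Without replicate 3 of every segment, 10 lists were called between caput and corpus. The 4 added there were the secreted ribonuclease family, serine protease inhibitors, immediate early and stress genes and ciliated cell markers, and the cause was not tested. Lists not called in the report were called under some alternatives, such as beta-defensins (higher in corpus) between corpus and cauda and smooth muscle and clear cell markers (higher in cauda) between caput and cauda.

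With the replicate number as a replicate block, 8446, 5946 and 8089 genes changed, 10129 differed among the segments and 8, 7 and 11 lists were called. Between corpus and cauda the block ended the calls of lipocalins, Hox genes and sperm-binding proteins (camera adjusted p of 0.0714, 0.0501 and 0.332) and added fibroblast markers, and between caput and corpus it added ribonucleases and ciliated cell markers. The numbers were not taken to pair the libraries. Across genes over 20 CPM, deviations from segment means correlated at -0.033 to 0.29 over 9 same-number pairs, 6 of them over 0.1, and at -0.27 to 0.19 over 18 other pairs, and 7 of 9 libraries were closest to their own number.

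Of 357 changes of named genes, 343 were called, and none of these 343 changed sign in 6391 values under alternatives. Of those values, 6284 kept direction and side of the threshold, 91 fell short of it (60 of them on leaving out 1 library), 5 passed it and 11 changed sign. The 11 belonged to changes not called. Rn45s from caput to corpus was -0.09 with the replicate block, -0.27 without replicate 3 of every segment, -0.08 with RPKM denominators, and -0.44 to 0.45 on leaving out 1 library. Itm2b from caput to corpus was -0.03 with RPKM denominators. From corpus to cauda, Lcn8 was -0.23 without replicate 3 of every segment. On leaving out 1 library that change was -0.3 to 0.64 for Lcn8, -0.08 to 0.46 for Spag11b and -0.45 to 0.16 for Ovch2. The cause of these changes of sign was not tested.

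Alternatives written for normalized values were not run, since the counts were used. At this depth, 1 count is 0.165 to 0.385 CPM before TMM scaling, and genes with few counts have wide bounds.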

Other observations

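All families were tested and their members chosen after the data were seen, as were the tests of stroma, of caput tissue and of cell types, while the splits of the libraries and the test of transcript length and GC content over all segments were chosen before. Counting only mixed groups and setting the pairs with cauda apart were also chosen after. Gene families were taken as symbols with a common stem and at least 8 tested genes, 233 families in 3 segments or 699 Fisher's exact tests, one-sided for a higher share. Caput-enriched genes made up 9.92% of tested genes but 17 of 33 Defb genes (Fisher's exact adjusted p = 1.37e-06), 8 of 18 Sema genes (adjusted p = 0.0428) and 44 of 255 Slc genes (adjusted p = 0.0428). The Slc stem includes 4 symbols of regulators or antisense genes, such as Slc9a3r2, and leaving these out gave 43 of 251 (Fisher's exact adjusted p = 0.0593) and ended the Sema call as well (adjusted p = 0.0564), so that only the Defb call held. No family passed for corpus or cauda. The same test by chromosome, two-sided, called none, the lowest adjusted p being 0.181 (106 of 813 genes on chromosome 1 for caput).

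The grouping of the libraries was set against other splits. Among the 280 splits of the 9 libraries into groups of 3, 100 were compared. The real split gave 9782 genes that differ among groups and the highest other split 4913, so that 1 split was as large. Every other split mixes segments, however, which widens the spread inside its groups and lowers its count. Caput-, corpus- and cauda-enriched genes numbered 1405, 567 and 518, against 1389 in the largest group of the highest other split, so that 1, 5 and 5 of the 100 splits were as large. That largest group holds the 3 caput libraries and repeats their count, as do the 4 other splits that exceed the corpus and cauda counts, which points to the structure of the samples. Groups that mix segments gave at most 0 by edgeR, and 37 at an unadjusted p under 0.05, but their large inner spread leaves little room for a call. These splits therefore do not decide whether chance can be excluded, for the genes that differ among groups or for the enriched counts.

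Fits of the 6 libraries of a pair of segments gave 7737, 5201 and 7720 changed genes for caput and corpus, corpus and cauda, and caput and cauda, and at least 2-fold changes in 3490, 1887 and 3365 genes. The highest other of the 10 splits gave 0 in each case by edgeR, with 187, 399 and 304 genes at an unadjusted p under 0.05, so that 1 split was as large each time. Those fits called 8, 10 and 11 lists, against 8, 7 and 8 in the highest other split, with 2, 1 and 1 splits as large. Splits of 10 are too few for a share under 0.05.

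The replicate 3 libraries of the 3 segments deviated together from replicates 1 and 2. Of 8229 genes above 20 CPM, 8174 (99.3%) had a transcript length and GC content. Over these, the deviations correlated between segments at a mean of 0.22 (95% bootstrap interval over genes 0.18 to 0.25). The intervals resample genes as if independent and do not measure the spread between libraries, since each segment has 1 replicate 3 library. After correction for transcript length and GC content in the same genes, the mean was 0.16 (0.12 to 0.2). In these libraries that argues against length and GC content as the whole cause. This rests on caput with corpus, which went from 0.28 to 0.25 (0.21 to 0.29). Corpus with cauda went from 0.17 to 0.1 (0.045 to 0.16) and caput with cauda from 0.2 to 0.13 (0.075 to 0.18), so that length and GC content stay open for the pairs with cauda. In caput, corpus and cauda the deviation correlated with length at Spearman's rho of 0.18, 0.2 and 0.42, and with GC content at -0.25, -0.06 and -0.13. A lower share of stroma as a whole is argued against in cauda by smooth muscle markers, whose median deviation there was 0.71 with 12 of 12 above 0. In caput and corpus it stays open, since smooth muscle (-0.41 and -1.48), fibroblast (-0.44 and -0.98) and endothelial markers (-0.39 and -1.08) were lower there, beside -0.06 and -0.01 for macrophage markers. Endothelial markers were lower in cauda too (-0.37, 8 of 9 below 0), so a lower share of endothelial cells stays open in all 3 segments. A shared preparation or animal stays open, and no biological explanation was tested.

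In 398 genes corpus lay at least 2-fold below both caput and cauda. Clu (10900, 179 and 2270 CPM), Spink5 (1290, 46.7 and 1570), Hoxb9 (146, 24.9 and 160) and Cldn4 (190, 42.1 and 147) are examples, chosen after their values were seen. Caput tissue carried into the cauda libraries would bring all abundant caput transcripts. The share was set from 38 caput-enriched genes of at least 1000 CPM, with the 398 genes themselves left out. In those 38 genes cauda stood at a median of 0.16% of caput, ranging from 0% to 39%. The median share covers the cauda excess of 3 genes, Rnase10 among them. They make up 0.77% of the 389 whose lowest cauda value exceeds the highest corpus value. Fewer stromal and immune cells in corpus would lower all their markers there by about the 1 log2 unit of the pattern on both sides. Median changes from caput were 0.64 for fibroblast, 0.2 for endothelial (interquartile range -0.48 to 0.56) and -0.22 for macrophage markers (-0.73 to 0.21), and from corpus to cauda 0.52 (0.44 to 0.75), -0.36 (-0.58 to -0.15) and 0.35 (0.17 to 0.45). This argues against such cells as the whole cause, while a smaller shortage of macrophages in corpus, whose marker medians were lower there on both sides, stays open. Smooth muscle markers changed by a median of -0.84 from caput to corpus, with 3 of 12 lower and 1 higher, and of 2.73 from corpus to cauda. Actg2, one of them, went from 1240 CPM in caput to 17.2 in corpus and 205 in cauda. For Actg2 this argues against a lower share of smooth muscle as the whole cause. That share stays open for muscle genes such as Tpm1 (364, 144 and 515 CPM). A difference between the segments themselves stays open, untested.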
